A study of Rattus norvegicus with 20 samples.

How the data were processed

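Total RNA from 20 epididymal samples of male rats was measured on strips of the Rat Gene 2.1 ST array made by Affymetrix, 1 array per sample. The sample titles name 4 groups of 5 arrays: lean control, obese, rosiglitazone and resveratrol. Those titles do not call the treated rats obese, and they are taken here as obese rats given each compound. Titles number the arrays of each group as biological replicates, and no label pairs them across groups. Per the labels' protocols, the animals were ZDF rats kept under a reversed cycle of 12 h light and 12 h dark, with the strain given as Zucker. Lean rats ate a standard chow and obese rats a stock diet for 6 weeks. The dose, route and duration of rosiglitazone and resveratrol, and the diet of the treated rats, are not given in the sources used here. Tissue was snap-frozen, RNA was extracted with TRIzol and RNeasy columns with a DNase step, and 100 ng per sample was converted to biotinylated target, per the labels' protocols.

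The deposited table holds log2 signal values for 36685 features and 20 arrays, and the authors made it with RMA, per the submitters' processing notes. The version of that tool was not given. The values ran from -0.17 to 12.5 and the array medians from 2.50 to 2.74. All 20 columns were mapped to a sample and no 2 columns were identical. No normalization, filter or offset was added for the main analysis. The number of arrays limits the precision: the median standard error of a log2 difference between groups of 5 was 0.17.

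Features were paired with genes through the array annotation held with the series, in which 14824 probe sets named exactly 1 gene, 829 named several and the remaining 21032 features named none. For 234 genes with more than 1 probe set, the probe set with the highest mean over all 20 arrays was used, giving 14557 genes. Gene symbols were checked against a RefSeq table of the rat assembly GRCr8, which was used only for names and for gene order, and no coordinates are printed. Lepr and Pparg had no probe set paired with them alone and were not analysed here. Genes for olfactory, vomeronasal and taste receptors served as a measure of background: 1280 were measured, with a median of 1.54 and a 95th percentile of 3.10. Means under that percentile, which held for 7544 genes, are called near background, and a fold with 1 such mean is approximate, as background signal enters it.

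Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed in writing. Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted over all 20 arrays, moderated variances and Benjamini-Hochberg adjustment over all genes, at an adjusted p threshold of 0.05. The 6 comparisons were obese with lean control, each treatment with obese, each treatment with lean control, and rosiglitazone with resveratrol. Adjusted p-values in the text come from this model unless another is named, and they measure the spread between these arrays. Errors of log2 differences are standard errors of the model and errors of group means are SD with n = 5. Plots were drawn with matplotlib 3.10.9.

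For 37 gene lists, the members past the threshold were counted, both adjusted over all genes and adjusted over the list alone. Of 912 entries, 672 were measured. One macrophage entry of the written plan ran the symbols Clec7a and Lgals3 together; the list as tested held both, of which Lgals3 was measured. Each list was also tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance. Simulated arrays with known changes showed that camera at the preset correlation called a mean of 4.5 of 33 unchanged lists in the resveratrol and obese design, against 0 with an estimated correlation. A list shifted by 0.5 log2 units was recovered in 100% of draws at the preset correlation and in 30% with an estimated one, so a list that does not pass with an estimated correlation is not shown to be unchanged. Lists are therefore described by member counts and by the p-value with an estimated correlation.

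The scripts were tested on simulated data made from the real means and spreads, with 200 changed genes in each of 20 draws. Changed genes were drawn only from those brighter than the median gene, so recovery among dimmer genes was not tested. All 200 changes were present at once, which eases the Benjamini-Hochberg threshold. Recovery where only a few genes change was not tested and may be lower. Changes of 1.5-fold, 2-fold, 3-fold and 4-fold were recovered in 20.3%, 77.7%, 98.3% and 99.4% of genes for obese and lean control, in 16.4%, 81%, 97.7% and 99.5% for rosiglitazone and obese, and in 18.4%, 81.4%, 98.8% and 99.9% for resveratrol and obese. For rosiglitazone and resveratrol the shares were 17.7%, 80.3%, 98.5% and 99.7%.

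Genes named in the text were the 10 with the highest and the 10 with the lowest log2 difference among those past the threshold whose 2 groups of arrays did not overlap, leaving out placeholder symbols, chemoreceptors and receptor segments. Where no gene passed, the 5 with the smallest p were taken. From each list up to 4 members past the threshold were added, or up to 2 with the smallest p where none passed, and Lep and Adipoq were reported throughout. Genes outside this rule are stated to have been chosen after their values were seen.

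Genes returned toward lean were those past the threshold in obese rats and again, with the opposite sign, under treatment. Because both comparisons use the same obese arrays, the count was set beside 100 simulations with all 4 groups unchanged, and the overlap of independent sets. Obese and lean rats did not differ in these simulations either, so they could not test this count. The 20 splits of the obese arrays into sets of 2 and 3 could not test this count, as the median number of genes called between obese and lean rats was then 0. The similarity of the 2 treatments was measured as a Pearson correlation and a covariance of log2 differences across genes. The splits of obese arrays and the simulations with unchanged groups were references, and genes are not independent replicates. The alternatives were a fit on only the 2 groups compared, the replicate number as a block, trended and robust variances, array weights, a filter removing the dimmest genes (1 in 3), quantile normalization of genes, subtraction of array medians, the mean of several probe sets, all features in place of genes, a 1.5-fold threshold, and each array left out in turn. The signal SD of each array as a covariate and the removal of lean control replicate 3 from comparisons that do not use it were added after the data were seen. Other splits of the arrays of each comparison were counted in 100 draws.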

Results

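Gene expression in epididymal tissue was compared between lean control rats, obese rats, and obese rats given rosiglitazone or resveratrol, with 5 arrays per group. Rosiglitazone is an insulin-sensitizing drug that activates the nuclear receptor PPAR-gamma, the regulator of fat cell formation. Resveratrol is a plant polyphenol studied for effects on sirtuins and energy metabolism. The labels give the tissue only as epididymal. Genes typical of fat cells were bright, with Adipoq (the hormone adiponectin) at 10.97 ± 0.06 log2 units in obese rats (SD, n = 5), while 22 measured genes of the epididymal epithelium and sperm averaged 1.57 ± 0.12, near background. Spearman correlations between arrays ran from 0.920 to 0.980. The first principal component carried 34.1% of the variance and the next 13.4%. On the first component rosiglitazone arrays averaged 30.8 ± 5.64, resveratrol arrays 0.807 ± 9.24, obese arrays -2.96 ± 11.1 and lean arrays -28.6 ± 25 (SD, n = 5 each). Within groups this component tended to rise with the signal SD of the array. Lean control replicates 4 and 3 lay at -49.7 and 11.8, with signal SD 1.73 and 1.91. Obese replicates 1 and 3 lay at -14.5 and 9.49, with 1.83 and 1.93. The order of the groups on it is thus not separate from signal range.

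**Figure D1:**
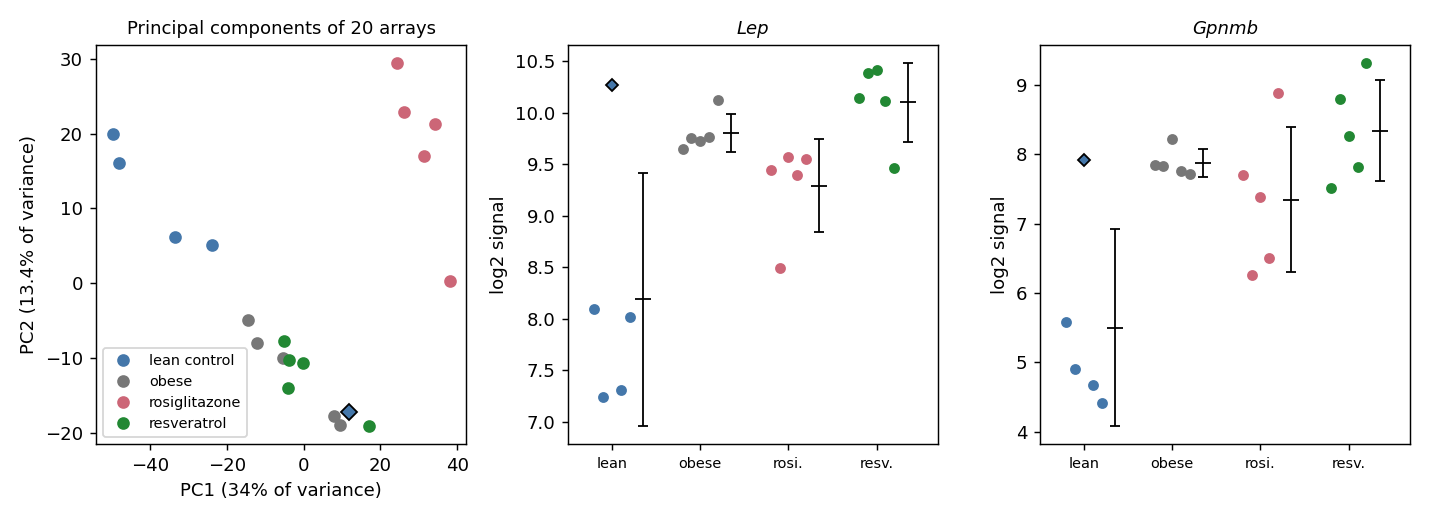
Left, the first and second principal components of the 20 arrays, 1 point per array, coloured by group; middle and right, log2 signal of Lep and Gpnmb in each array, with bars for the mean and SD of 5 arrays and lean control replicate 3 drawn as a black-edged diamond. That array lay at 10.3 for Lep, above the obese arrays (9.65 to 10.1), and at 7.92 for Gpnmb, among the obese arrays (7.72 to 8.22), while the other 4 lean arrays stayed at or below 8.10 and 5.59.

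Obese and lean rats were compared to find the expression changes that accompany obesity in this model. The labels give these groups different diets, a standard chow for lean and a stock diet for obese rats. Any effect of diet therefore cannot be told apart from that of obesity. Obese rats had higher expression of Lep, the fat cell hormone that signals energy stores, at 9.80 ± 0.18 against 8.19 ± 1.23 log2 units in lean rats (SD, n = 5 each), a 3.06-fold difference (log2 difference 1.61 ± 0.36, adjusted p = 0.0417). Gpnmb rose 5.18-fold (adjusted p = 0.0305), Lyz2 3.34-fold (adjusted p = 0.0368) and Lgals3 2.78-fold (adjusted p = 0.0456). The lipid droplet coat gene Plin2 rose 3.32-fold and Olr1, a receptor for oxidized lipoprotein, 4.48-fold (adjusted p = 0.0164 for each). In Lep, Gpnmb, Lyz2, Lgals3, Plin2 and Olr1 the groups overlapped, because lean control replicate 3 had obese-like levels. The lean mean of Olr1 was near background, so its fold is approximate. Adiponectin did not differ (Adipoq log2 difference 0.00, adjusted p = 0.995).

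Among genes whose lean and obese arrays did not overlap, Plet1 rose 9.11-fold (adjusted p = 0.0166), the metal-binding metallothionein Mt2A 7.72-fold and the transcription factor gene Dmrt2 2.84-fold (adjusted p = 0.00639 for both). The glutamate transporter gene Slc1a3 fell by 1.51 on the log2 scale, 2.85-fold, with the same adjusted p. The angiopoietin gene Angpt4 was 2.43-fold lower and Vipr2, a receptor for vasoactive intestinal peptide, 2-fold lower. The lower group mean of Plet1, Dmrt2 and Vipr2 was near background, so their folds are approximate. Cfd, the adipokine adipsin, was 2.16-fold lower (adjusted p = 0.0164), with overlapping groups. Across the array 105 of 14557 genes differed, 85 higher and 20 lower, of which 48 by at least 2-fold and 38 without overlap between the groups. Over all genes tested, 310 (2.13%) had no overlap, where chance gives 0.794%. With quantile normalization of the genes those called were 43 higher and 29 lower.

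Of 26 measured macrophage genes 5 were higher and none lower in obese rats, and 10 were higher adjusted over the list alone (median log2 difference 0.55, adjusted p = 0.747 with an estimated correlation). Of 15 cholesterol synthesis and uptake genes 2 were higher, the feedback regulator Insig1 (2.04-fold) and the synthesis enzyme Msmo1 (1.83-fold), and 7 were higher adjusted over the list alone (adjusted p = 0.609 with an estimated correlation). Of 35 PPAR target genes 2 were higher and 7 were higher over the list alone (adjusted p = 0.747 with an estimated correlation). Fibroblast and preadipocyte genes had 1 of 19 higher, the Wnt-binding protein gene Sfrp1 at 3.14-fold, with 9 higher and 2 lower adjusted over the list alone (adjusted p = 0.747 with an estimated correlation). Medians of these 4 lists stayed positive under quantile normalization, median subtraction and the covariate for array signal SD. In oxidative phosphorylation no member of 41 passed with limma, and its median of 0.27 turned negative under the covariate (adjusted p = 0.756 with an estimated correlation). At the preset correlation camera called 10 of 37 lists and with an estimated correlation 0, as did fry. For the brown and beige adipocyte, triglyceride synthesis, lipolysis and inflammatory cytokine lists the median, mean and test differed in sign.

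The number of genes called in obese rats depended on single arrays. Without lean control replicate 3 the count was 1856, and without lean control replicates 1, 2, 4 and 5 it was 18, 5, 6 and 8. Leaving out obese replicates 1 to 5 in turn gave 42, 24, 4, 40 and 9. With the SD of each array as a covariate no gene passed in limma, where 2651 genes had an unadjusted p under 0.05 without it. Lep passed in 7 of 19 alternatives, with adjusted p from 3.97e-06 without lean control replicate 3 to 0.482 with the covariate, and Mt2A, Slc1a3 and Dmrt2 in 18 of 19.

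Rosiglitazone and obese arrays were compared to find what the drug changed in obese rats. Most measured genes of fatty acid oxidation, 22 of 24, were higher with the drug, although the list as a whole did not pass with an estimated correlation (adjusted p = 0.0634). Fabp3, a carrier of fatty acids typical of heart and brown fat, rose 29.6-fold to 8.60 ± 0.41 from 3.72 ± 0.34 log2 units (SD, n = 5 each; adjusted p = 1.29e-11). Cpt1b, the gate for fatty acid entry into mitochondria, rose 7.46-fold (adjusted p = 3.34e-09). Me1, which supplies reducing power for fat synthesis, rose 9.31-fold (adjusted p = 1.09e-06), and the glucose transporter gene Slc2a4 rose 2.11-fold (adjusted p = 0.00157). Cdh5, the adhesion protein of vessel lining, fell by 1.38 on the log2 scale (2.60-fold, adjusted p = 1.63e-06) and Col14a1, a fibroblast collagen, fell by 2.92 (7.59-fold, adjusted p = 1.5e-06). In each of the genes Fabp3, Cpt1b, Me1, Slc2a4, Cdh5 and Col14a1 all 5 rosiglitazone arrays lay beyond all 5 obese arrays.

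**Figure D2:**
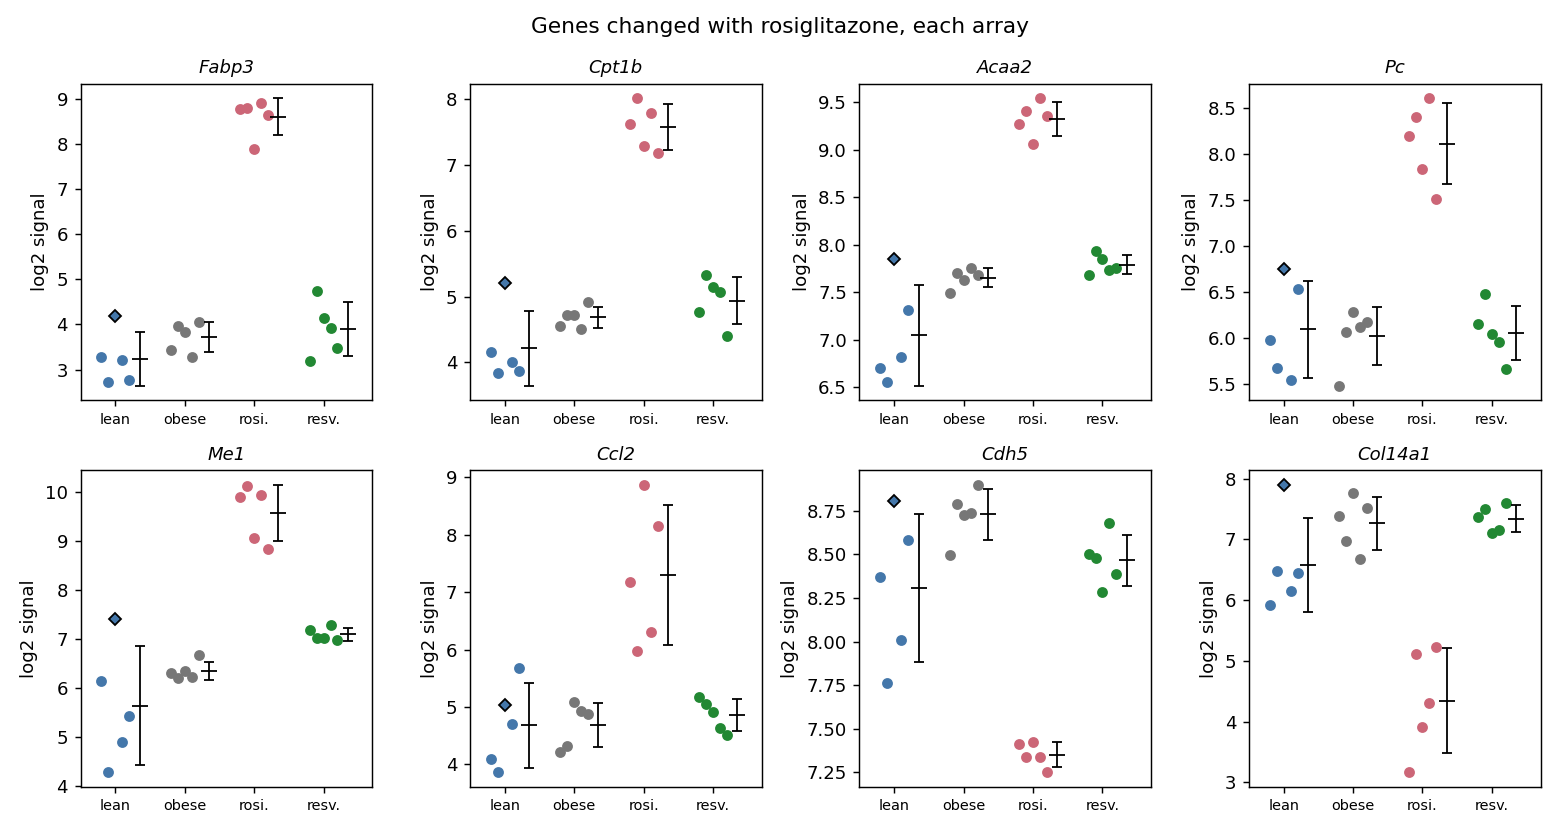
Log2 signal of 8 genes in each array, 1 point per array, grouped as lean control, obese, rosiglitazone and resveratrol, with bars for the mean and SD of 5 arrays and a black-edged diamond for lean control replicate 3. In the rosiglitazone group Fabp3 averaged 8.60 and Cdh5 7.35, against 3.72 and 8.73 in the obese group, with no overlap between these groups in any of the 8 genes.

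Across the array 1310 genes changed with rosiglitazone, 920 higher and 390 lower, and 988 of them had no overlap between the groups. Over all genes tested, 1478 (10.2%) had none, where chance gives 0.794%. Of the 1310 called genes 364 changed at least 2-fold. With quantile normalization 748 were called higher and 661 lower, and with the covariate for array SD 950 and 609. The count of called genes stayed between 1018 and 1598 when any 1 array was left out.

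Of 24 fatty acid oxidation genes 22 rose and none fell (23 and 0 adjusted over the list alone), among them Acadl (3.20-fold), the carnitine carrier Slc25a20 (3.16-fold) and Acaa2 (3.18-fold), with a median log2 change of 1.38. Of 15 genes of the tricarboxylic acid cycle and pyruvate metabolism 14 rose, both over all genes and adjusted over the list alone, including pyruvate carboxylase Pc (4.27-fold, adjusted p = 9.15e-07), Suclg1 (2.66-fold) and Pdha1 (2.2-fold). Oxidative phosphorylation had 33 of 41 genes higher and none lower (37 and 1 over the list alone), with Ndufa9 at 2.39-fold and Uqcrc2 at 2.32-fold. Branched-chain amino acid breakdown had 15 of 21 higher (18 over the list alone), led by Acat1 (3.33-fold) and Acadsb (2.66-fold). PPAR targets had 19 of 35 higher and none lower (22 and 1 over the list alone), with the fatty acid transporter Slc27a1 at 4.90-fold. In fatty acid synthesis 9 of 14 rose (10 over the list alone), including Elovl6 (7.86-fold), Pnpla3 (5.59-fold) and Acss2 (2.93-fold). The direction of each of these lists was the same under quantile normalization, median subtraction and the array SD covariate.

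With an estimated correlation the adjusted p was 0.0634 for both fatty acid oxidation and the tricarboxylic acid cycle, 0.0939 for PPAR targets, 0.0975 for fatty acid synthesis, 0.10 for oxidative phosphorylation and 0.110 for branched-chain amino acid breakdown. Brown and beige adipocyte genes passed (adjusted p = 0.0116), with 9 of 16 higher and 2 lower (10 and 2 adjusted over the list alone). As written, that list shared Fabp3, Cpt1b, Cidea, Pdk4, Gk, Ucp3 and Fgf21 with the PPAR targets, so its result is not separate from theirs. It also held Ppara, the fatty-acid-sensing receptor (2.63-fold, adjusted p = 1.85e-05). Ucp1, the uncoupling protein of brown fat, rose 2.11-fold (adjusted p = 0.000317) but stayed near background in both groups, at 2.43 ± 0.46 against 1.35 ± 0.31. Camera at the preset correlation called 17 of 37 lists, fry 12 and camera with an estimated correlation 1.

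Endothelial markers fell in 8 of 16 genes and rose in 1 (10 and 1 over the list alone), with Cldn5 5.05-fold lower (adjusted p = 2.52e-07), Emcn 2.48-fold lower and Sox17 2.33-fold lower (adjusted p = 0.0832 with an estimated correlation for the list). Fibroblast and preadipocyte genes had 8 of 19 lower and 1 higher (8 and 2 over the list alone; estimated correlation adjusted p = 0.414). The stem and progenitor marker Cd34 was 3.64-fold lower and Lum 4.04-fold lower, and Ccn5 rose 5.40-fold (adjusted p = 1.55e-07). Both lists kept their direction under the scaling alternatives. Outside the lists, Nnat (neuronatin) was 8.51-fold lower, the adipokine C1qtnf9 7.99-fold lower and the peptidase Ace 6.42-fold lower, while Vat1l rose 11.1-fold, the retinol-converting enzyme Rdh12 8.25-fold and the junction protein gene Dsp 8.12-fold. The lower group mean of Cldn5, C1qtnf9, Vat1l, Rdh12 and Dsp was near background, so their folds are approximate. Albumin (Alb) rose 25.2-fold, from 4.71 ± 1.62 to 9.37 ± 0.48 (adjusted p = 1.11e-06).

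Few inflammatory genes passed. The monocyte attractants Ccl2 (6.11-fold, adjusted p = 6.66e-05) and Ccl7 (3.93-fold, adjusted p = 0.00115) rose, and they were the 2 members higher among 26 inflammatory cytokine and acute phase genes, with 1 lower (adjusted p = 0.797 with an estimated correlation). The obese mean of Ccl7 was near background. No macrophage gene of 26 passed in limma (median -0.22), although camera called that list lower at the preset correlation. The macrophage call ended without rosiglitazone replicate 2 (adjusted p = 0.226), rosiglitazone replicate 4 (0.224), obese replicate 3 (0.102) or obese replicate 5 (0.0602), and with an estimated correlation (0.689). The mean of that list was 5.952 in rosiglitazone replicate 5, against 4.595 to 5.17 in the other rosiglitazone arrays and 4.991 to 5.545 in obese arrays. Lep (log2 change -0.51, adjusted p = 0.468) and Adipoq (-0.02, adjusted p = 0.959) did not pass. Cfd rose 1.72-fold (adjusted p = 0.0128), a call lost under quantile normalization (adjusted p = 0.16, the highest of a range from 0.00195).

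Antioxidant and xenobiotic genes rose in 8 of 27 (13 over the list alone), including the mitochondrial enzymes Sod2 (3.12-fold, adjusted p = 1.57e-06) and Prdx3 (2.63-fold), with adjusted p = 0.414 for the list at an estimated correlation. Extracellular matrix had 7 of 25 higher and 1 lower (9 and 1 over the list alone), with Thbs2 4.04-fold, Loxl1 3-fold and Ccn2 2.87-fold higher and Mmp2 2.25-fold lower (adjusted p = 0.527 with an estimated correlation). Cholesterol synthesis had 3 of 15 higher (7 over the list alone), insulin signalling 5 of 17 (7 and 1 lower over the list alone) and the sirtuin, AMPK and mitochondrial biogenesis list 3 of 18 (6 over the list alone). With an estimated correlation their adjusted p was 0.428, 0.512 and 0.428. Smooth muscle and pericyte genes had 3 of 11 lower and 1 higher, and adipocyte identity 3 of 18 higher, with a median of 0.09 that turned negative under quantile normalization (adjusted p = 0.414 and 0.797 with an estimated correlation). Adipokines had 2 of 21 higher and 1 lower, triglyceride synthesis 2 of 12 higher, lipolysis 1 of 12 higher and 2 lower, and mesothelial genes 2 of 14 higher. Immediate early genes had 3 of 16 higher and the circadian, endoplasmic reticulum stress, blood, and leptin and PPAR receptor lists 1 higher each. The neutrophil, skeletal muscle and class II lists had 1 lower each. In limma no member passed in the T and NK cell, B cell, mast cell, epididymal, cell cycle, interferon and ribosomal lists, where limma gave 3095 genes with an unadjusted p under 0.05 over the whole array. For the lists from adipokines to ribosomal genes the adjusted p with an estimated correlation ran from 0.428 to 0.967. The median, mean and test differed in sign for 7 lists, none of them called by camera: lipolysis, neutrophil, mesothelial, epididymal, skeletal muscle, blood and circadian.

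**Figure D3:**
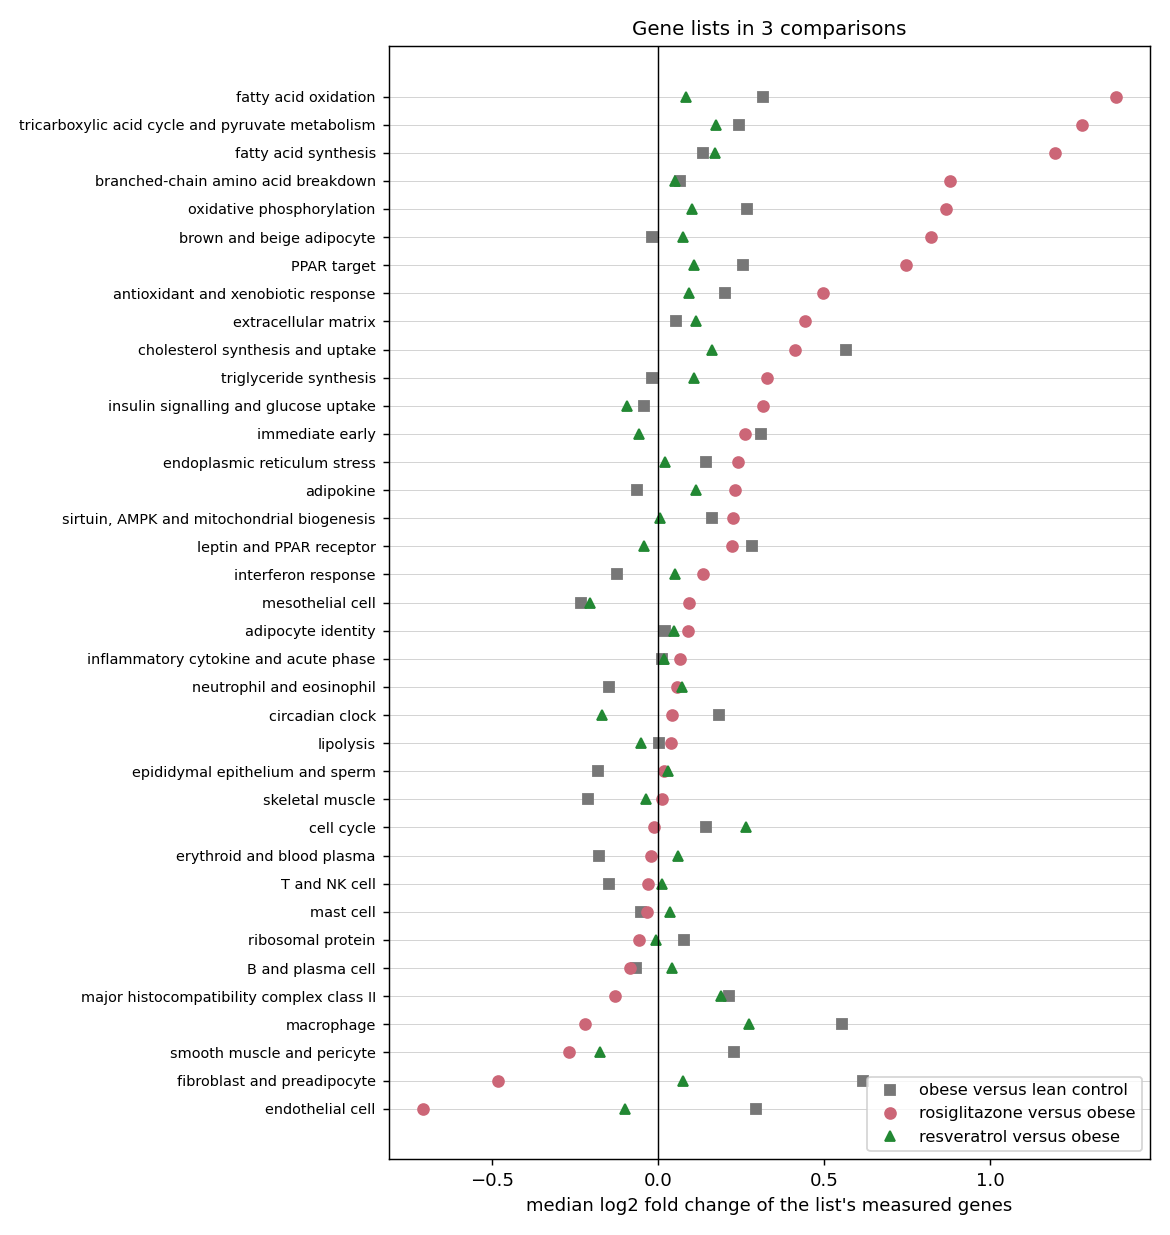
Median log2 fold change of the measured members of each of 37 gene lists (horizontal axis), 1 line per list, with squares for obese versus lean control, circles for rosiglitazone versus obese and triangles for resveratrol versus obese. Fatty acid oxidation had the highest circle at 1.38 and endothelial genes the lowest at -0.71, both with the same sign under every scaling alternative.

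Resveratrol and obese arrays were compared to find what this compound changed. No gene passed in limma, and the 410 genes with an unadjusted p under 0.05 made up 2.82% of the 14557 tested. The smallest adjusted p was 0.999. Genes with the smallest p were the receptor genes Mas1l (log2 difference -0.68 ± 0.17) and Gabra3 (-0.74 ± 0.19, near background), the cytochrome P450 gene Cyp2d1 (0.70 ± 0.19), Zbed3 (-0.61 ± 0.17) and Clec4a2 (0.58 ± 0.17, near background). Lep was at 10.1 ± 0.38 with resveratrol and 9.80 ± 0.18 without it (log2 difference 0.30), Adipoq differed by 0.06 and Me1 by 0.75, with adjusted p = 0.999 for each.

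For 14350 genes, 98.6% of those tested, the 95% interval of the resveratrol effect lay within 2-fold in either direction, and for 11119 (76.4%) within 1.5-fold. Among the genes tested 7544 had a mean near background, where background signal enters the fold and a narrow interval does not bound the change in RNA. The shares were not computed for genes above background alone. Groups did not overlap in 87 genes, 0.598% of those tested, where chance gives 0.794%. The count stayed at 0 in limma under every alternative run, including each array left out. No list had a member past the threshold in limma. Camera at the preset correlation called 7 of 37 lists, the cell cycle, macrophage, tricarboxylic acid cycle, fatty acid synthesis, oxidative phosphorylation and cholesterol lists higher and the endothelial list lower, and 0 with an estimated correlation (adjusted p of 0.738 or higher) or with fry. Median log2 differences of the called lists ran no higher than 0.27 and, for endothelial genes, stood at -0.10. The number of lists called was 11 without resveratrol replicate 1, 4 without resveratrol replicate 2 and 3 without obese replicate 1. For the skeletal muscle, blood, sirtuin and ribosomal lists the median, mean and test differed in sign.

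Rosiglitazone and resveratrol arrays were compared directly, which tests whether the treatments differ. Fabp3 was 26.1-fold higher with rosiglitazone (8.60 ± 0.41 against 3.89 ± 0.60, SD, n = 5 each; adjusted p = 1.78e-11) and Cpt1b 6.25-fold higher (adjusted p = 1.76e-08). Albumin (Alb) was 44.5-fold higher, the adipokine Cfd 2.02-fold higher (adjusted p = 0.00182), the carbonyl reductase Cbr1 7.80-fold higher and the matrix protein gene Cilp 7.15-fold higher. Lower with rosiglitazone were C1qtnf9 (8.08-fold), Col14a1 (8.0-fold), Nnat (6.83-fold) and Cldn5 (5.09-fold, adjusted p = 3.42e-07). The macrophage survival gene Cd5l was 2.81-fold lower (adjusted p = 0.00591) and the class II chaperone Cd74 1.82-fold lower (adjusted p = 0.0073), with overlapping groups in both. The rosiglitazone mean of C1qtnf9, Cldn5 and Cd5l was near background, so their folds are approximate.

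In total 1100 genes differed between the treatments, 820 higher with rosiglitazone and 280 lower, 823 of them without overlap between the groups. Arrays of the treatments did not overlap in 1156 of all genes tested (7.94%, with 0.794% by chance). With quantile normalization 580 were called higher and 506 lower, and with the array SD covariate 675 and 516. Of the 1100 genes 899 were also called for rosiglitazone against obese. Fatty acid oxidation had 22 of 24 genes higher (22 over the list alone; estimated correlation adjusted p = 0.0697), oxidative phosphorylation 29 of 41 (36 higher and 2 lower over the list alone; 0.142) and PPAR targets 18 of 35 (19 over the list alone; 0.135). Brown and beige genes, with 8 of 16 higher and 2 lower, passed with an estimated correlation (adjusted p = 0.0238). Endothelial genes had 7 of 16 lower and 1 higher (estimated correlation adjusted p = 0.135). Macrophage genes had 1 of 26 lower, and 4 adjusted over the list alone (median -0.54, estimated correlation adjusted p = 0.346), with 7 lower under quantile normalization and 10 with the array SD covariate. For the lipolysis, T and NK cell, skeletal muscle and blood lists the median, mean and test differed in sign.

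Each treatment group was also compared with lean rats, which shows what still set treated obese rats apart. With resveratrol the macrophage genes Gpnmb (7.17-fold, adjusted p = 0.0051) and Lyz2 (3.92-fold), the lipid droplet gene Plin2 (4.10-fold) and Lep (3.76-fold, adjusted p = 0.00872) were higher than in lean rats, with overlapping groups. Mt2A (8.24-fold) and Cd5l (4.11-fold) were higher and Slc1a3 (3.73-fold), Cfd (2.54-fold) and the activin receptor gene Acvr1c (3.06-fold) lower without overlap, with the lean mean of Cd5l near background. In total 383 genes differed, 304 higher and 79 lower, 104 without overlap (294 of all genes tested, 2.02%, with 0.794% by chance), and 77 of those called also differed between obese and lean rats. Macrophage genes had 10 of 26 higher (16 over the list alone; estimated correlation adjusted p = 0.474) and cholesterol genes 6 of 15 (10 over the list alone; estimated correlation adjusted p = 0.474). The split was 240 higher and 133 lower under quantile normalization, and with the array SD covariate 6 and 5. The count was 2073 without lean control replicate 3 and 135, 113, 102 and 193 without lean control replicates 1, 2, 4 and 5. Without resveratrol replicates 2, 3, 4 and 5 it was 133, 178, 248 and 169.

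With rosiglitazone 3632 genes differed from lean rats, 2678 higher and 954 lower, of which 1535 had no overlap (1613 of all genes tested, 11.1%, with 0.794% by chance). Under quantile normalization 1466 were higher and 1327 lower, and with the array SD covariate 614 and 502. Fabp3 was 41.3-fold, Mt2A 18.9-fold, Olr1 17.7-fold and Me1 15.2-fold higher, and the B cell attractant Cxcl13 4.67-fold and the lactate receptor Hcar1 4.01-fold lower. The lower group mean of Olr1 and Cxcl13 was near background, so their folds are approximate. Fatty acid oxidation had 23 of 24 genes higher (24 over the list alone; estimated correlation adjusted p = 0.160), and macrophage genes 5 of 26 (5 over the list alone; estimated correlation adjusted p = 0.743), with a median of 0.32 that turned to -0.13 with the array SD covariate. Lep was 2.15-fold higher than in lean rats (adjusted p = 0.0282), and with the array SD covariate its log2 difference was -0.10 (adjusted p = 0.902, the highest of a range from 6.12e-06).

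Genes altered in obesity and moved back by treatment were then counted. With rosiglitazone 14 genes moved in the opposite direction to the change in obese rats and 15 moved further in the same direction. Among those that returned were Slc1a3 (log2 -1.51 in obese rats, then 1.19), the amino acid transporter Slc36a2 (-1.51, then 1.96), Cbr1 (-1.98, then 2.86) and Cfd (-1.11, then 0.78). Olr1 and Loxl1 were among those that moved further from lean. Slc36a2, whose obese mean was near background, was chosen after its values were seen. In simulations with all 4 groups unchanged the median was 0 genes and the highest 2 with opposite signs, and 0 with the same sign. Obese and lean rats did not differ in them either, so a count near 0 was fixed in advance and cannot serve as a reference. Independent sets would share 3.54 genes with opposite signs and 5.91 with the same sign. They share no arrays, whereas the obese arrays enter these 2 comparisons in opposite directions, which by itself favours opposite signs. In the simulations the log2 differences of the 2 comparisons had a median r of -0.503 (-0.761 to -0.177). The 3.54 is thus too low a reference, and the 14 genes are not shown to exceed what sharing gives.

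When 1 array was left out the count of 14 ranged from 1 to 108 and the 15 that moved further from 0 to 326. Without lean control replicate 3, 108 returned and 326 moved further, and without rosiglitazone replicate 5, 27 returned and 15 moved further, so the balance depended on single arrays. The count returned was 4 without lean control replicate 1, and 1 without lean control replicate 2, 4 or 5. Without obese replicates 1 to 5 it was 6, 3, 1, 6 and 1. Leaving out rosiglitazone replicates 1 and 3 gave 9 and 8, and leaving out resveratrol replicates 2, 3 and 4, which enter through the shared spread, gave 9, 5 and 7. With resveratrol 0 genes returned, as no gene passed in limma against obese arrays.

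The responses to both treatments were set side by side, to see whether they changed the same genes. Across genes the log2 changes against obese arrays had a Pearson r of 0.343 with a jackknife SD of 0.137. Simulations with all 4 groups unchanged, in which both comparisons shared a group, gave a median r of 0.525 (0.168 to 0.751). Neither treatment had an effect in them, so these values of r are not like for like. The covariance of the changes was 0.0227, within the simulated range (mean 0.0199, 0.00597 to 0.0492). With separate obese arrays the median was 0.127 (-0.0753 to 0.196), and genes are not independent replicates. Of the 1310 genes called with rosiglitazone, 980 had the same sign with resveratrol and 330 the opposite, which the shared obese arrays also favour. Among these Fabp3 changed by 4.89 with rosiglitazone and by 0.18 with resveratrol, and Nnat by -3.09 and -0.31.

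**Figure D4:**
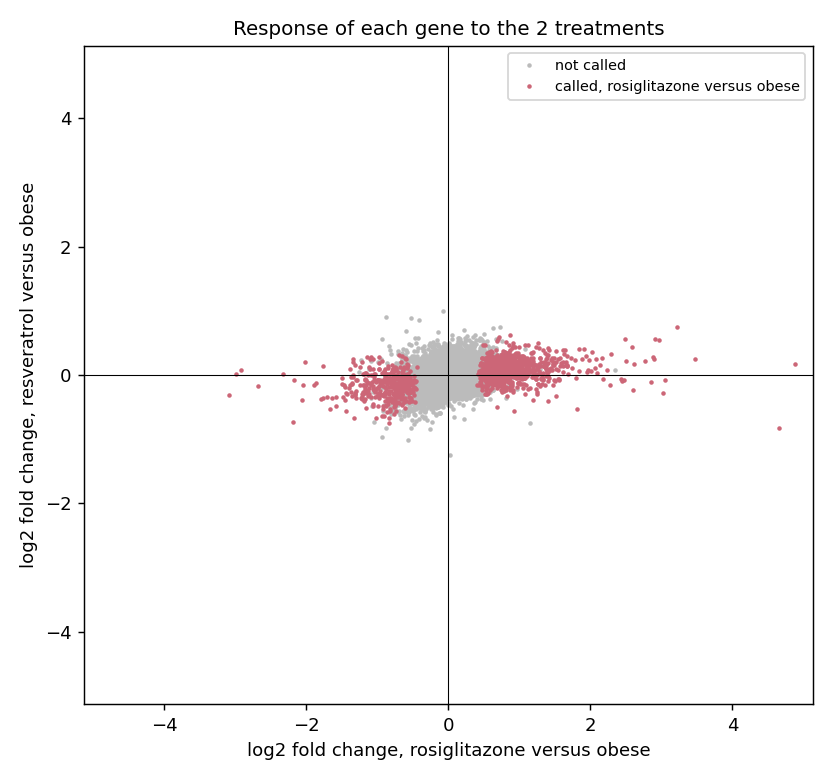
Log2 fold change of each of 14557 genes with resveratrol (vertical axis) against that with rosiglitazone (horizontal axis), both relative to obese arrays, 1 point per gene. Coloured points are the 1310 genes called with rosiglitazone, which spread to 4.89 along the horizontal axis, while no gene was called with resveratrol.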

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

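The tests of a swap and of a wider signal range for lean control replicate 3, of dilution by fat cells and of liver RNA were chosen after the result was seen. Of 472 groups of 5 arrays examined, 36 held an array far from the other 4 by Dixon's test, where chance would give 23.6, about 1 in 20, and 13 of the 36 were lean control replicate 3. The flags of other arrays, listed below, may therefore be chance.

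Lean control replicate 3 stood apart from the other 4 lean arrays in Lep (10.3, others 7.24 to 8.10), Olr1 (4.20, others 2.14 to 2.40), Plet1 (4.84), Dmrt2 (3.27), Sfrp1 (6.13), Cpt1b (5.21), Col14a1 (7.90), Lum (7.48) and Cilp (4.85), and was lower in Acvr1c (6.53, others 7.62 to 7.83). Its mean was higher in the fibroblast list (6.60) and the cell cycle list (3.01) and lower in the skeletal muscle list (2.21). On a score of genes that separate obese from the other lean arrays, with each obese array in turn left out of the choice of genes, obese arrays reached 2.86 to 3.45 and lean control replicate 3, also left out, 3.33 to 3.42. The highest of the other 4 lean arrays, which entered that choice, reached 1.77 to 2.24. A swap with an array of another group would need a partner with lean-like values, and 0 of the 15 other arrays lay within the lean range. The signal SD of lean control replicate 3 was 1.91, against 1.73 to 1.81 in the other lean arrays. A wider signal range of that array would not lower bright genes that are lower in obese rats, whose median shift was -0.69 against -0.10 to 0.15 in the other lean arrays. Those genes were chosen with the other 4 lean arrays and without replicate 3, which by itself favours a lower value in replicate 3.

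A single wrong label for lean control replicate 3, or a swap with a sample outside the series, may explain the pattern. Of 59 measured neighbours of Lepr, the gene mutated in this strain, 6 separated the other lean arrays from the 15 arrays of the other groups, and in all 6 it lay nearer to the 15. That test was weak, since the same held for 93.8% of the 727 separating genes anywhere, and the share of separating genes, 10.2% of the neighbours against 4.99% of all genes, left open whether neighbours were enriched (Fisher's exact test, two-sided p = 0.0731). A lean rat with an obese-like fat depot stays open as an untested biological explanation.

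Endothelial and fibroblast markers averaged lower with rosiglitazone, by a mean of -0.79 in 15 endothelial and -0.50 in 18 fibroblast genes above background. Each list also held a gene called higher, and neither list passed with an estimated correlation. A wider array range is argued against, since 8 of 8 endothelial genes called lower stayed lower with the array SD as a covariate and their list median went from -0.71 to -0.81. Dilution by more or larger fat cells could lower every other cell type alike. Among genes above background, 9 of smooth muscle changed by a mean of -0.30, 21 of macrophages by -0.24 and 9 mesothelial genes by -0.19. Over all 14 measured mesothelial genes the mean was 4.003 with rosiglitazone and 3.985 in obese arrays, so that sign depended on the genes taken. An exact one-sided permutation test of the spread over the 5 lists (SD 0.247, 126 splits) gave p = 0.111. Tested in pairs, with an exact permutation p that allows for all 10 pairs, endothelial minus smooth muscle means were -0.59 to -0.46 in rosiglitazone and -0.07 to 0.09 in obese arrays (p = 0.00794). Equal dilution as the whole cause is thus argued against for endothelial markers, by the spread over arrays. Over genes, by an exact two-sided rank-sum test not adjusted over pairs, the same pair had p = 0.0552, and endothelial against macrophage and mesothelial genes p = 0.000427 and 0.0101. Over arrays these 2 pairs overlapped between the groups (permutation p = 0.524 and 0.317), so 1 of 3 pairs goes against equal dilution there. Fewer endothelial cells and lower expression in them stay open and were not tested. For fibroblast markers the smallest pair p against the 3 lists outside the pattern was 0.571, so with 5 arrays for each group dilution and a change in these cells cannot be told apart.

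Albumin (Alb) rose by 4.66 on the log2 scale with rosiglitazone. Liver RNA in those samples is a candidate source, but 11 liver genes had a median change of 0.00 (0.00128, SD 0.174) and 0 of them passed in limma, where 3095 genes had an unadjusted p under 0.05 in this comparison. Expression of Alb in the tissue itself and cross-hybridization of its probes stay open and were not tested.

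Among obese arrays, replicate 1 was low for the triglyceride synthesis list (5.62), the inflammatory cytokine list (3.01), Pc (5.48) and Nnat (10.1). Obese replicate 3 was high for Gpnmb (8.22, others 7.72 to 7.84). Obese replicate 4 was low for the mast cell list (2.0) and Angpt4 (3.52) and high for Adipoq (11.1). Obese replicate 5 was high for Lep (10.1, others 9.65 to 9.77) and Slc25a20 (4.48).

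Among rosiglitazone arrays, replicate 2 was low for Lep (8.49, others 9.39 to 9.57). Replicate 3 was low for Fabp3 (7.88) and high for Slc1a3 (6.10). Replicate 5 was high for the neutrophil list (2.14), Mmp2 (7.50) and Cd5l (3.99, others 1.79 to 2.25). Among resveratrol arrays, replicate 2 was high on the first principal component (17.0, others -5.09 to -0.188), the fatty acid synthesis list (6.67), the fibroblast list (6.54) and Prdx3 (6.45). Resveratrol replicate 1 was high for Mt2A (7.25) and low for Loxl1 (5.79), and resveratrol replicate 5 was low for Acss2 (5.70).

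The 2 treatment groups differed from each other in 1100 genes, a difference tested directly. Of 21861 features paired with no single gene, 7 passed in limma between obese and lean rats and 338 between rosiglitazone and obese rats, a signal in data outside the gene comparisons.

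Other splits of the same arrays into 5 and 5 were counted, 100 for each comparison with the real one included. For rosiglitazone and obese 1 split, the real one, gave as many as 1310 genes (highest other 10), and for rosiglitazone and resveratrol 1 gave 1100 (highest other 62). For rosiglitazone and lean control 1 gave 3632, with 3304 in the split that exchanged lean control replicate 3 with a rosiglitazone array. In each of these 3 comparisons the real split gave the highest count of the 100 drawn, out of 126 possible. Chance is thus argued against, although the splits not drawn were not counted. For obese and lean control 5 splits gave 105 or more (highest other 2385), and for resveratrol and lean control 5 gave 383 or more (highest other 1728), so chance cannot be excluded. The highest of these put lean control replicate 3 with the obese or treated arrays and 1 array of those with the lean arrays, which points to a structure of the samples. For resveratrol and obese the real count in limma was 0 (410 genes at an unadjusted p under 0.05), which all 100 splits reach by necessity, so that test says nothing.

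For the numbers of lists called with camera at the preset correlation chance cannot be excluded in any comparison. Obese and lean control gave 10, reached by 44 splits (highest other 21), rosiglitazone and obese 17, by 8 (20), and resveratrol and obese 7, by 26 (19). Rosiglitazone and resveratrol gave 17, by 14 splits (21), rosiglitazone and lean control 16, by 17 (21), and resveratrol and lean control 13, by 34 (26).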

How the results depend on the processing

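Alternatives with the array SD as a covariate, or without lean control replicate 3 in comparisons that do not use it, were chosen after the result was seen. Gene counts for rosiglitazone and obese, resveratrol and obese, and rosiglitazone and resveratrol stayed within 1.5 times of 1310, 0 and 1100 in each alternative, and 72 of 88 named genes called with rosiglitazone against obese passed in each one. For obese and lean control, with 105 genes, the count was 31 with only those groups fitted, 166 with the replicate block, 51 with trended and robust variances, 1102 with array weights, 13 over all features, 0 with the array SD covariate in limma (2651 with an unadjusted p under 0.05 without it), and 4 to 1856 with 1 array left out. As the covariate called 0, no single gene could pass in each alternative there. For rosiglitazone and lean control, with 3632, it was 1116 with the covariate and 5691 over all features. For resveratrol and lean control, with 383, it was 74 with only those groups fitted, 970 with array weights, 11 with the covariate, 98 over all features and 102 to 2073 with 1 array left out. Array SD differed between groups (lean 1.80 ± 0.07, obese 1.88 ± 0.04), so the covariate also removes part of the group difference; the cause of the other shifts was not tested. With an estimated correlation the lists called fell to 1 for rosiglitazone against obese or resveratrol and to 0 in the 4 other comparisons. In obese and lean control 10 lists became 3 without the dimmest genes and 4 with the covariate. In resveratrol and obese 7 became 12 with the covariate and 3 to 11 with 1 array left out, and in resveratrol and lean control 13 became 8 with the covariate. Genes returned with rosiglitazone ran from 1 to 108, and genes moved further from 0 to 326, with 1 array left out. With the obese arrays divided 0 returned, which says nothing about sharing, since the median number of genes called between obese and lean rats was then 0. The correlation of the treatments was 0.127 with divided obese arrays, in place of 0.343; dividing them both ends the sharing and leaves fewer obese arrays in each comparison, and these effects were not separated. The sign of Lep reversed between rosiglitazone and lean control with the covariate (-0.10, adjusted p = 0.902, from a range of 6.12e-06 to 0.902). Replicate numbers did not pair the arrays: each was closest to its own number in 4 of 30 pairings, where chance gives 6. Signal over background limits genes under 3.10, which held for 7544 of 14557.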

Other observations

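Of the 19 alternatives, that with the array SD as a covariate was chosen after the result was seen; the genes follow the rule for naming genes. Hcar1, the lactate receptor, was 2.08-fold lower with rosiglitazone than in obese rats (adjusted p = 0.00457) and 2.25-fold lower with resveratrol than in lean rats (adjusted p = 0.0119). Hcar2, the ketone body and niacin receptor, was 2.54-fold lower with rosiglitazone (adjusted p = 0.00134) and 2.40-fold lower with resveratrol (adjusted p = 0.0216) than in lean rats. The resveratrol differences in Hcar1 and Hcar2 passed in 18 and 14 of 19 alternatives. Hcar1 and Hcar2 differed by -0.95 and -1.0 on the log2 scale between obese and lean rats, short of the threshold (adjusted p = 0.0596 and 0.0884), and no gene passed in limma between resveratrol and obese rats (410 at an unadjusted p under 0.05), so a lowering by resveratrol itself was not shown.

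The lipid droplet gene Cidea was 7.29-fold higher with rosiglitazone (adjusted p = 1.79e-06) and 2.65-fold higher with resveratrol (adjusted p = 0.0331) than in lean rats. The second of these passed in 8 of 19 alternatives, with adjusted p from 1.28e-06 to 0.325. Rrm2, an enzyme of DNA precursor synthesis, was 3.55-fold higher with resveratrol than in lean rats (adjusted p = 0.00783) and 2.43-fold lower with rosiglitazone than with resveratrol (adjusted p = 0.0187), passing in 18 and 15 of 19 alternatives, with its lean mean near background. Without lean control replicate 3, Cidea was also higher in obese than in lean rats, by 1.655 on the log2 scale. As no gene passed in limma between resveratrol and obese rats (410 at an unadjusted p under 0.05), an effect of resveratrol itself on Cidea or Rrm2 was not shown. Ppargc1a, a coactivator of mitochondrial genes, rose 1.86-fold with rosiglitazone (adjusted p = 0.00936) while near background in both groups. The early response gene Ier3 rose 2.07-fold (adjusted p = 0.00035), with no overlap between rosiglitazone and obese arrays.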
